A study of Homo sapiens with 4 samples.

How the data were processed

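The series holds 4 nylon filter arrays of HUVEC RNA, 1 for each of 4 groups: control monosome, control polysome, serum monosome and serum polysome. Groups were taken from the sample titles. Per the labels, cells were treated with cycloheximide, which halts ribosomes on mRNA, and lysates were centrifuged through sucrose gradients. RNA of the monosome or polysome part was copied from oligo-dT primers into cDNA that carried a radioactive phosphorus label, and filters were read with a phosphorimager and the array maker's software. The intensity values were deposited after division by a constant per filter. Per the labels, that constant was the average signal of the filter, but the median of every deposited column was 1.0 and the means ran from 1.78 to 2.08, so the values fit division by the median. No background values were used here, and no subtraction shows in the intensities, whose lowest values were 0.46 to 0.58. Most elements lay close to the median (25th percentile 0.82 to 0.89, upper quartile 1.19 to 1.44). Where such elements held mostly background, their ratios were drawn toward 1 and understate any difference.

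Gene names came from the platform annotation supplied with the values and were updated through a RefSeq gene table (GRCh38.p14), used for names only. Of 4132 elements, 1582 had a single gene symbol, 52 had several and were not named, and 2498 were unlisted in that annotation and are unnamed here. Of the single-symbol elements, 1580 matched the gene table. No genomic coordinates are given, since the values carry none.

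Each intensity was divided by the mean of its filter, as the submitters describe. Each ratio is therefore relative to the filter means, and a ratio of 1 does not mean equal amounts. A shift of all mRNAs between fractions would not show. The translation state was the polysome value over the monosome value, and the translation index was the serum translation state over the control translation state. The serum to control ratio within each fraction was also taken, which made 5 ratios. The limits of 2.5 and 0.4 are those of the submitters. Their criterion of signal over background above 1.1 was not applied. In its place an element had to exceed the 25th percentile of each of the 4 filters, which kept 1905 elements (678 with a single symbol, from 663 genes) and removed 2227. This filter also removes elements that drop to background on any filter. Without it the index was high for 60 elements and low for 74.

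With 1 filter per group there is no replicate to leave out, and the index leaves no residual degree of freedom. A fit of fraction and serum as main effects over the 4 filters would leave 1 residual degree of freedom, with their interaction as its error, and was not run, so all ratios are described without p-values. The sole repeat measurement was that of different elements of the same gene (12 genes, 27 elements), whose pooled SD of log2 ratios is given as the error of an element. For the index its bootstrap interval over genes was 0.32 to 0.66. Most of these elements were dim, and the error of bright elements can differ. Elements of the same gene were averaged on the log2 scale for gene lists. A list's median was ranked among 10000 random lists of the same size drawn within 10 intensity bins, which describes these filters and is not a test of the conditions. Intervals of correlations came from 2000 bootstrap draws of elements, and intervals of shares are exact binomial.

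Before the data were examined, the groups, filter, limits, 25 gene lists, named-gene rule and most alternatives were fixed. The rule named the 12 highest and 12 lowest single-symbol elements past an index limit, the 6 highest and 6 lowest of each other ratio, the highest, lowest and median member of each list, and 29 fixed genes. The alternatives were no filter, a filter at the filter medians, a floor at the 25th percentile, division by the median, quantile normalization, a loess correction of each ratio on mean intensity, a pseudocount at the 10th percentile, limits of 2 and 0.5, and the brightest element of each gene. A further 3 were chosen after seeing the data: elements above 1.5 times the filter median on at least 1 filter, the same on all 4 filters, and subtraction of the filter median with differences under 0.25 set to 0.25.

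The calculation was tested on simulated data for the index, with 50 elements changed at each fold, noise of 0.2 on the log2 scale and 1927 elements past the filter. Of elements changed 2-fold, 4.0% were past the limit, against 78.0% at 4-fold and 82.0% at 8-fold. Of elements lowered to 0.125 of their value, 4 of 50 passed the filter and all 4 were past the limit, since the rest fell below the filter. Of 1792 unchanged elements, 1 (0.06%) was past a limit. The noise was set per filter and not estimated from these data. The index combines 4 filters, so its simulated error was larger than 0.2, and 0.2 is not comparable with the SDs of the index that follow. In the data the log2 index had an SD of 0.49 between elements of the same gene, and 1.06 with signal on at least 1 filter. The simulated shares therefore check the calculation and do not give the error rate of these filters. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.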

Results

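Translation state was measured in primary human umbilical vein endothelial cells (HUVEC), which line the vein of the umbilical cord. Growth-arrested cells in medium with 0.1% pooled human serum were compared with cells given 20% pooled human serum. The design text gives 6 h of serum, whereas the sample labels describe an overnight treatment, and the files do not settle which applies. Lysates were separated on sucrose gradients, and RNA was taken from the monosome fraction (mRNA with a single ribosome) and the polysome fraction (mRNA with several ribosomes). Each of the 4 RNA samples was labelled with a radioactive nucleotide and hybridised to its own nylon filter of 4132 cDNA elements, so each group held 1 filter. No group had a replicate, no test between groups was run, and every difference is given as a ratio with no replicate check and no p-value. The number of filters limits the precision.

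The deposited intensities had a median of 1.0 on every filter. Their mean was 1.94 in control monosomes, 2.07 in control polysomes, 1.78 in serum monosomes and 2.08 in serum polysomes. More elements stood clear of the bulk on the polysome filters. Intensity exceeded 1.5 times the filter median for 968 elements in control polysomes (23.4%, exact 95% interval 22.1 to 24.7) and 943 in serum polysomes (22.8%, 21.5 to 24.1). The same held for 562 elements in control monosomes (13.6%, 12.6 to 14.7) and 537 in serum monosomes (13.0%, upper bound 14.1). These intervals cover counting error over elements and not the spread between cultures. Across elements, log2 intensities of the polysome filters correlated with r = 0.9 between conditions and those of the monosome filters with r = 0.89, against r = 0.79 between the fractions within either condition. By rank the polysome filters had a Spearman correlation of 0.75, but the monosome filters had 0.54, no higher than between the fractions (0.54 in control and 0.56 in serum). Elements are not independent replicates.

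The ratio of polysome to monosome signal (the translation state) asks how far each mRNA was loaded with ribosomes in growth-arrested cells, relative to the average element. Each filter was scaled to its own mean, so the folds below are relative and 1 does not mean equal amounts in the fractions. PTMA, which encodes the nuclear protein prothymosin alpha, was 7.47-fold higher in control polysomes than in control monosomes. ARPC2, a subunit of the complex that branches actin filaments, was 7.25-fold higher, and PEA15, a phosphoprotein of the death effector domain family, 5.79-fold higher. SNRPD2, a core protein of the spliceosome, was 5.48-fold higher, and ARHGDIB was 5.46-fold higher. The cytoskeletal gene ACTB gave 5.35-fold and 5.14-fold at its 2 elements. At the other end, PTPA, an activator of a serine/threonine phosphatase, had a polysome to monosome ratio of 0.113 in control cells, and the neurotrophic factor receptor GFRA2 had 0.216. Ratios were 0.233 for SMARCC2 and 0.275 for SMARCD2, both subunits of chromatin remodelling complexes. The actin-associated gene SYNPO had 0.244, and PPP1R10, a nuclear regulator of a protein phosphatase, had 0.281. In the fraction with the lower signal, ARPC2 (1.15) and ARHGDIB (1.21) in monosomes and PPP1R10 (0.872) in polysomes lay near the filter median. The sizes of these ratios therefore depend on how background is handled. The lower intensity of each other element named here was about 1.5 or more.

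Of 1905 elements that passed the intensity filter, 141 (7.4%) lay at or above 2.5 in control cells and 36 (1.9%) at or below 0.4, the limits the submitters set for their index. Between elements of the same gene the SD of this log2 ratio was 0.51, a factor of 1.42 (12 genes, 27 elements), against 0.74 over all elements. That SD is the error of an element on these filters and not the spread between cultures. The excess of high over low ratios depended on the scaling of the filters, with 73 high and 59 low after quantile normalization and 58 high and 67 low after a loess correction. The counts were 71 and 22 with a pseudocount. With the filter median subtracted as background they were 465 and 124, but among the 1277 elements above 1.5 times the median on at least 1 filter. Under division by the median, quantile normalization and loess, the 12 genes named above kept their direction, and SMARCD2 did not stay past the limit under all of these.

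In serum-treated cells, the highest translation state among the 678 elements with a single gene symbol belonged to GRIA2, a glutamate receptor subunit best known from neurons, at 9.16. FGF1, a growth factor that stimulates endothelial proliferation, had 7.83 and PTMA had 7.57. RAB9A, which directs transport from late endosomes to the Golgi, had 6.34. The transcription factor MEF2D had 6.05 and the gap junction gene GJB1 had 5.94. Serum monosome intensities of GRIA2 (0.999), FGF1 (1.06), MEF2D (1.1) and GJB1 (1.03) lay near the filter median. The sizes of their ratios therefore depend on how background is handled. Those of PTMA (1.59) and RAB9A (2.96) lay above it. The lowest ratio among these elements was 0.0555 for NPC1, which exports cholesterol from lysosomes. SMARCD2 had 0.134, MARCHF6, a ubiquitin ligase of the endoplasmic reticulum, had 0.148, and the stress-activated kinase gene MAPK8 had 0.152. RAB1A, which directs transport from the endoplasmic reticulum to the Golgi, had 0.179, and PTPA had 0.197. The serum polysome intensity of NPC1 was 1.06, near the filter median, while the other low genes named here had 2.58 or more. There were 114 elements (6.0%) at or above 2.5 and 32 (1.7%) at or below 0.4, and the SD between elements of the same gene was 0.43 on the log2 scale, a factor of 1.35. These counts became 64 high and 58 low after quantile normalization and 48 high and 54 low after loess. They were 60 and 23 with the pseudocount, and 362 and 138 among 1277 elements with the filter median subtracted. Dividing by the filter median moved the median log2 ratio of the 1905 elements from -0.05 to 0.17.

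Many elements kept their place between the fractions in both conditions. PTMA (7.47 in control, 7.57 in serum), ARPC2 (7.25, 4.34), PEA15 (5.79, 2.78), SNRPD2 (5.48, 4.83) and both ACTB elements (5.35, 3.29 and 5.14, 4.44) were past 2.5 in each. So were LDHA, a glycolytic dehydrogenase (2.69, 3.63), CCNI, a cyclin (2.67, 4.63), ESR1, the estrogen receptor (2.53, 5.8), and CYCS, the cytochrome of the respiratory chain (2.51, 4.58), which were chosen after their values were seen. LDHA had 3 elements, which disagreed, with control ratios of 2.69, 3.13 and 0.858. PTPA (0.113, 0.197), GFRA2 (0.216, 0.215), SMARCC2 (0.233, 0.242), SYNPO (0.244, 0.272), SMARCD2 (0.275, 0.134), PPP1R10 (0.281, 0.271), MARCHF6 (0.29, 0.148) and MAPK8 (0.29, 0.152) were at or below 0.4 in each. Their monosome intensities ranged widely, from 2.91 in control and 2.95 in serum for PPP1R10 to 114.0 and 107.0 for SMARCD2. MARCHF6 had 94.2 and 76.9, against 18.5 or less for ACTB. Whether these elements report only the named mRNA was not tested. Intensities near the filter median entered some of these ratios, such as 0.872 and 0.932 for PPP1R10 in polysomes and 1.07 for ESR1 in serum monosomes. In all, 61 elements were high in both conditions, where independent lists of these sizes would share 8.4, and 13 were low in both, where 0.6 would be shared. Only 2 elements were high in control and low in serum (2.4 by the same reckoning), and 3 the reverse (2.2). These expected counts take no account of signal level, and dim ratios can be drawn toward 1. Among the 1277 elements above 1.5 times the median on at least 1 filter, 62 were high in both (14.9 expected) and 17 low (1.7). Among the 352 above it on all 4 filters, 34 were high in both (9.9) and 10 low (0.9).

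Across the 1905 elements the log2 translation states of the 2 conditions, which share no filter, had r = 0.56 (95% bootstrap interval over elements 0.5 to 0.61) and a Spearman rank correlation of 0.53. After quantile normalization 23 elements were high in both conditions (2.5 expected) and 18 low (1.8), and after loess 23 (1.5) and 15 (1.9). With the filter median subtracted, among 1277 elements, 246 were high in both against 131.8 expected, and 39 low against 13.4. All genes named here kept their direction under division by the median, quantile normalization and loess, but PEA15, LDHA, CCNI, ESR1, CYCS, SMARCD2 and MARCHF6 did not stay past a limit in both conditions under all of them.

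**Figure D1:**
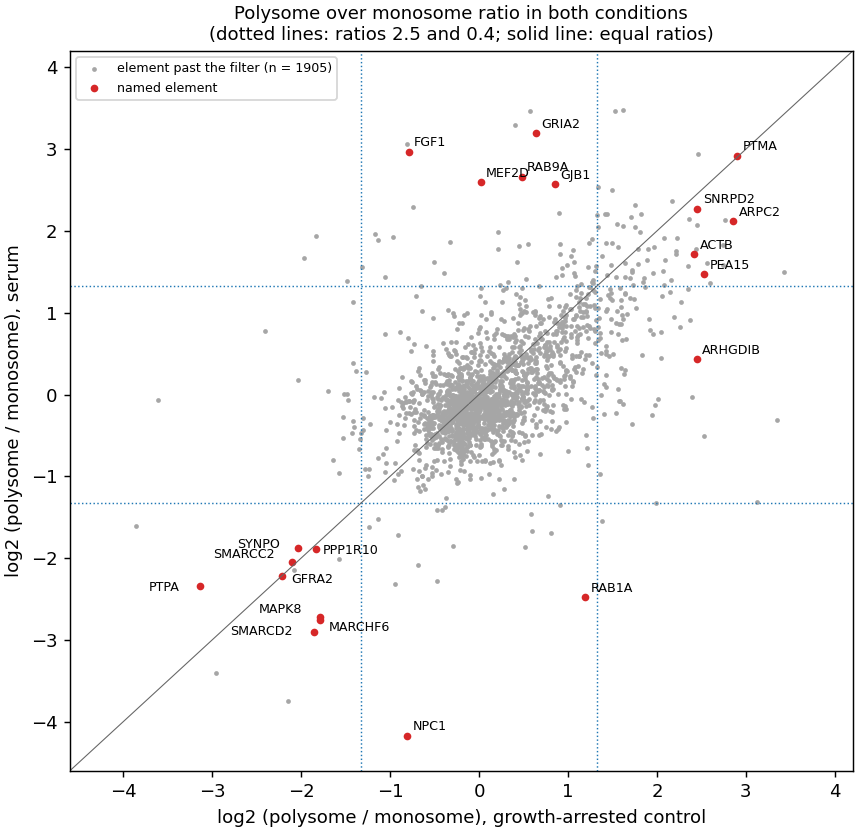
Polysome over monosome ratio (log2) in growth-arrested cells on the horizontal axis and in serum-treated cells on the vertical axis, with 1 point for each of the 1905 elements past the filter, named genes in red and dotted lines at ratios of 2.5 and 0.4. Points spread along the diagonal (r = 0.56), with PTMA at the upper right, PTPA at the lower left, and FGF1 and NPC1 far from the diagonal.

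The translation index, the serum translation state divided by the control translation state, asks which mRNAs differed in relative ribosome loading after serum. A shift of all mRNAs with serum would not show in it. FGF1 had the highest index of the named genes, 13.6, with intensities of 1.81 in control monosomes, 1.12 in control polysomes, 1.06 in serum monosomes and 9.7 in serum polysomes. Its control polysome and serum monosome intensities lay near the filter median, so the size of this index depends on how background is handled. PIGC, which acts in synthesis of the glycolipid anchor of membrane proteins, had an index of 8.8. FASTK, a kinase-family protein with roles in mitochondrial RNA, had 8.22, and the endoplasmic reticulum gene RTN3 had 8.11. MEF2D had 5.97, GRIA2 5.87, RAB9A 4.55, and MTR, the methionine synthase, 4.56. PSIP1, a chromatin-bound coactivator, had 3.41, MAP2K4, a kinase upstream of the stress-activated kinases, 3.36, GJB1 3.29 and the lysophospholipid acyltransferase gene MBOAT7 3.19. Polysome signal was not higher with serum for MAP2K4 (serum to control ratio 0.833) and MBOAT7 (0.714). Their intensities in control monosomes were 5.16 and 5.44, against 2.22 or less on the other filters.

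At the low end, RAB1A had an index of 0.0786, with intensities of 2.87 and 7.0 in control monosomes and polysomes and 12.3 and 2.58 in serum monosomes and polysomes. NPC1 had 0.097, and its intensity was 16.4 in serum monosomes against 1.06 in serum polysomes. MTMR11, of the myotubularin family, had 0.101 and the transcriptional repressor DR1 had 0.186. Indices were 0.21 for LDB2 and 0.235 for LMO2, both partners in LIM-domain transcription complexes, and 0.247 for the zinc finger gene ZNF148. The transporter gene SLC35B1 had 0.218 and the Notch ligand JAG1 had 0.232. CCN1, a secreted matricellular protein of the immediate early response, had 0.238, with intensities of 1.72 and 6.03 in control and 3.44 and 3.14 in serum. ARHGDIB had 0.247 and CYB561D2 had 0.295.

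An index at or above 2.5 was found for 48 elements (2.5%) and one at or below 0.4 for 50 (2.6%), of which 16 and 18 carried a gene name. The log2 index had an SD of 0.49 between elements of the same gene, a factor of 1.41 (12 genes, 27 elements), against 0.69 over all elements and limits at 1.32. Over the 1277 elements with signal on at least 1 filter that SD was 1.06. With the filter median subtracted over these same elements it was 1.53, above the limit. None of the 12 genes with several elements past the intensity filter had an element past a limit, so no call was repeated by another element. Elements of those genes could disagree in direction, with 1.01 and -0.39 for CHAF1B and 1.06 and -0.39 for DHPS on the log2 scale. Intensity exceeded 1.5 times the median on all 4 filters for FASTK, RTN3, MTR, RAB9A, RAB1A and CCN1, and on 3 for MBOAT7, LDB2 and ARHGDIB. It did so on only 2 filters for FGF1, PIGC, GRIA2, PSIP1, MAP2K4, GJB1, NPC1, MTMR11, DR1, LMO2 and ZNF148, and on only 1 for MEF2D, SLC35B1, JAG1 and CYB561D2. When the polysome serum ratios were shuffled among elements of similar intensity, 53.7 high (central 95% 45 to 62) and 58.4 low (50 to 68) calls arose on average over 1000 shuffles. The observed counts were no larger than random pairing of the fractions gave. Shuffling keeps every ratio of each fraction, so it cannot tell a change in a single fraction from error. The median log2 index was -0.12, which other scalings moved upward by 0.12 to 0.13, and the split was 57 high and 37 low with division by the filter median. It was 31 and 28 with the pseudocount, and 152 and 282 among 1277 elements with the filter median subtracted. The sizes of the indices moved with it, from a log2 of 3.76 for FGF1 to 6.54 with subtraction and 2.87 with the pseudocount, and from -3.67 for RAB1A to -4.8 and -3.19. MTMR11 (-3.31) was at -5.55 with subtraction, below RAB1A, but that value rests on the fixed minimum difference. Its intensities of 0.91 in control monosomes and 0.86 in serum polysomes lay below the filter median, so both differences were set to that minimum. FGF1 was set to it too, in control polysomes (1.12) and serum monosomes (1.06). The sizes of both with subtraction therefore depend on the minimum, and no change of order can be read from them. All 24 named genes kept their direction with subtraction, with the pseudocount and under the other scalings. CYB561D2 fell just short of a limit after quantile normalization (-1.32), and PSIP1 (1.25), MAP2K4 (1.29), MBOAT7 (1.23) and CYB561D2 (-1.28) lay within the limits with the pseudocount.

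**Figure D2:**
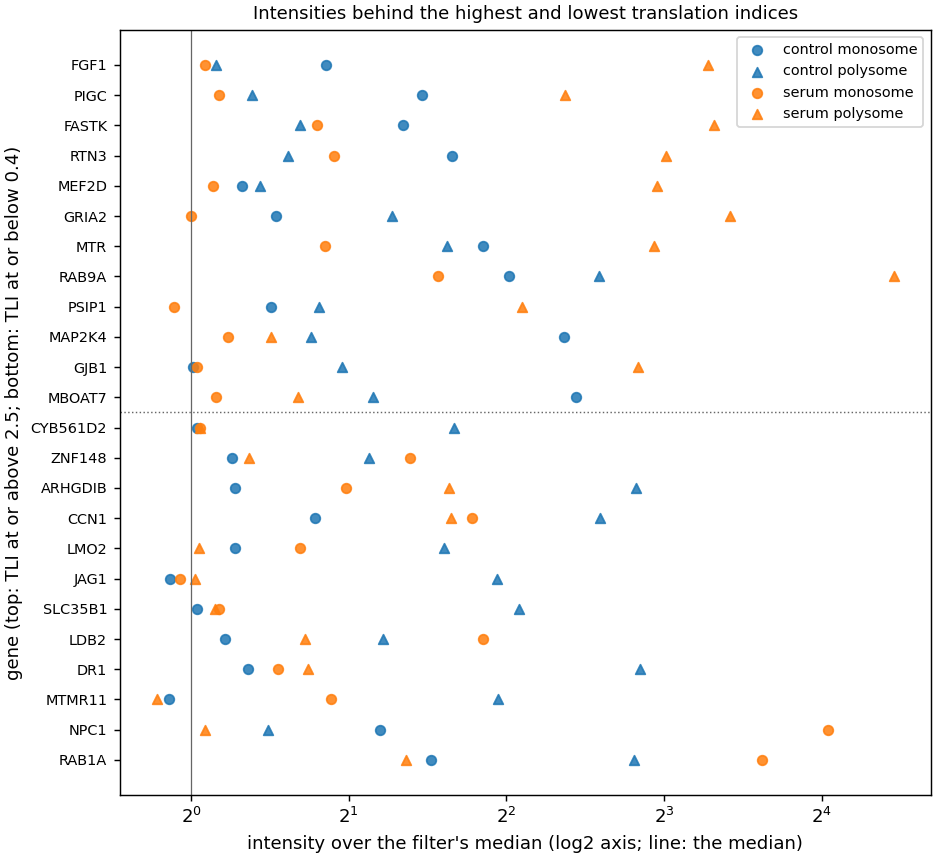
Deposited intensity (log axis, filter median 1) of the 24 genes with the highest and lowest translation index on the 4 filters, with 1 point per gene and filter and no error bars, since each group held 1 filter. FGF1 reached 9.7 in serum polysomes against 1.81 or less elsewhere, and NPC1 reached 16.4 in serum monosomes against 2.29 or less elsewhere.

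Serum-treated and growth-arrested cells were next compared within each fraction. In monosomes, NPC1 was 7.78-fold, RAB1A 4.66-fold and LDB2 3.38-fold higher with serum, and the Golgi-associated gene BLZF1 was 2.97-fold higher. The transcription factor genes MEF2A and ZNF148 followed at 2.38 and 2.37, short of the limit. Ratios of serum to control in monosomes were 0.224 for MBOAT7, 0.248 for MAP2K4, and 0.294 for PITPNM1, a phosphatidylinositol transfer protein. They were 0.332 for CDC34, a ubiquitin-conjugating enzyme, 0.369 for the membrane-bound metalloproteinase gene MMP15, and 0.398 for CSF1R, a receptor typical of macrophages. In polysomes, FGF1 was 8.64-fold, FASTK 6.13-fold, MEF2D 5.69-fold, RTN3 5.25-fold, GRIA2 4.39-fold and PIGC 3.93-fold higher with serum. The lowest polysome ratios of named elements were 0.222 for MTMR11, 0.231 for DR1, 0.262 for SLC35B1, 0.264 for JAG1, 0.325 for CYB561D2 and 0.338 for LMO2.

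Fewer elements passed the limits here than in the comparison of fractions. In monosomes 12 elements (0.6%) were high and 19 (1.0%) low, with an SD of 0.24 between elements of the same gene on the log2 scale, and in polysomes 25 (1.3%) were high and 32 (1.7%) low, with an SD of 0.38. Of the 83 elements past a limit in either fraction, 78 were past it in a single fraction. Of the other 5, 2 were high in monosomes and low in polysomes and 2 the reverse, where independent lists would share 0.2 each, and 1 was low in both (0.3) and 0 high in both (0.2). RAB1A, high in monosomes and low in polysomes, was the only one of the 5 with a gene name. Opposite limits were passed by 4 or more elements in 29 of 1000 shuffles among elements of similar intensity, with 1.1 on average and a central 95% of 0 to 4. Across elements the log2 serum to control ratios of the fractions had r = -0.02 (-0.09 to 0.05) and a Spearman rank correlation of 0.03. After loess the counts were 15 and 15 in monosomes and 30 and 25 in polysomes, and after quantile normalization 25 and 21 in polysomes. With the filter median subtracted, among 1277 elements, they were 118 and 78 in monosomes and 119 and 134 in polysomes. With the pseudocount they were 5 and 10 in monosomes and 20 and 13 in polysomes. Division by the filter median moved the median log2 ratio of monosomes from 0.09 to -0.03. CSF1R, MEF2A and ZNF148 in monosomes and CYB561D2 and LMO2 in polysomes were not past a limit under all of division by the median, quantile normalization and loess. Single genes were not followed under subtraction or the pseudocount for these ratios.

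**Figure D3:**
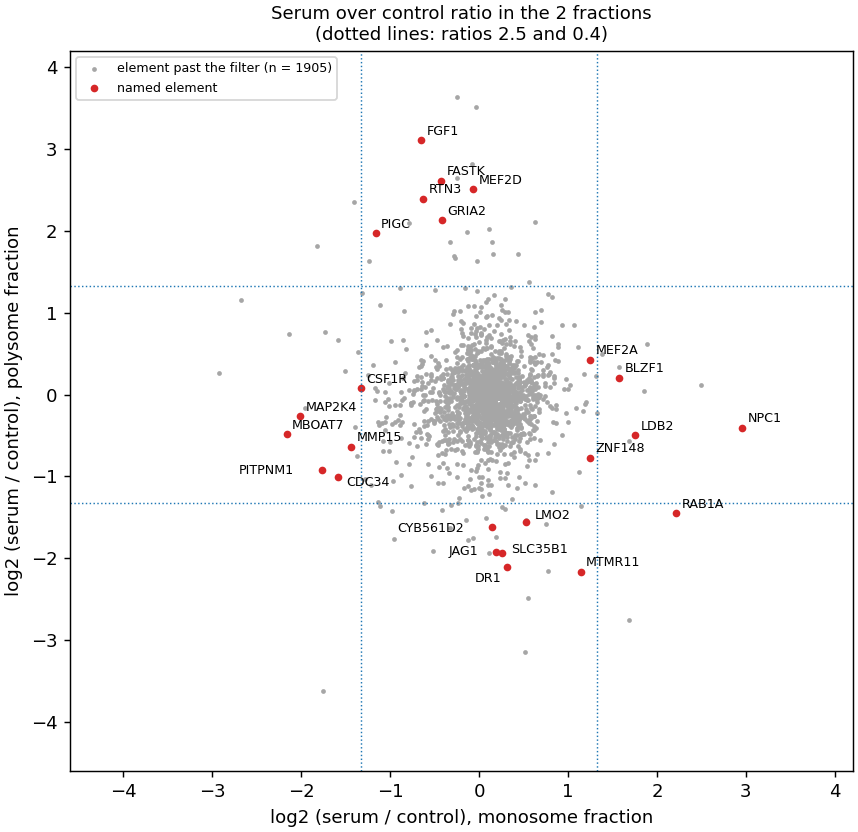
Serum over control ratio (log2) in the monosome fraction on the horizontal axis and in the polysome fraction on the vertical axis, with 1 point for each of 1905 elements, named genes in red and dotted lines at ratios of 2.5 and 0.4. Elements far from the centre lie mostly along 1 axis (r = -0.02), with FGF1 high in polysomes and NPC1 high in monosomes.

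Gene groups fixed beforehand were small on this array, and 12 of 25 lists had at least 3 genes past the filter. Several members lay near the filter median on all 4 filters, where ratios can hold mostly background. Among them were IRF1 (intensities 0.943 to 1.15), IFIT5 (0.831 to 1.07), AIMP1 (0.86 to 1.01), FLI1 (0.917 to 1.01) and COL6A2 (0.923 to 1.03). None of the 12 had a median translation index outside the central 95% of 10000 random lists matched on intensity. Among 9 immediate early genes, which respond to growth factors without new protein synthesis, 3 had an index above 1 and 6 below, with a median log2 index of -0.35 (percentile 11.5). CCN1 was the lowest at 0.238, KLF4 lay at 0.783, and JUNB was the highest at 2.44. The 3 genes of growth arrest were all below 1 (median log2 -0.55, percentile 8.5), with CCNG1 at 0.469, FOXO1 at 0.685 and the cyclin-dependent kinase inhibitor CDKN1B at 0.763. Among 5 genes of oxidative phosphorylation 1 was above and 4 below (-0.48, percentile 12.5), from CYCS at 1.83 through SDHC at 0.715 to NDUFA5 at 0.546. Among 5 extracellular matrix genes 1 was above and 4 below (-0.37, percentile 17.5), with NID1 at 1.71, COL6A2 at 0.774 and BGN at 0.672. These counts stand beside 756 elements above 1 and 1149 below among all 1905. The median of immediate early genes was 0.15 with signal on all 4 filters, where only CCN1, IER3 and JUNB remained. That value is the index of IER3, so it does not show a change of the list. With the filter median subtracted the median of immediate early genes was -0.65, and the medians of oxidative phosphorylation and extracellular matrix were -1.13 and -0.9.

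The proteasome genes had a median log2 index of 0.48 (percentile 89.8), with 2 above 1 and 1 below, namely PSMA1 at 1.65, PSME3 at 1.4 and PSME1 at 0.504. That median turned negative without the intensity filter (-0.13) and with a floor (-0.11), which let further members in. Cytoskeletal targets of serum response factor had 0.29 (percentile 71.1), with CALD1 at 1.64 and CNN1 at 1.22 above 1 and ACTB at 0.728 below. The 3 genes of aminoacyl-tRNA synthetase complexes were below 1 (-0.35, percentile 29.5), and so were the 4 genes of cholesterol synthesis (-0.17, percentile 49.4), with ACAT2 at 0.705, CYP51A1 at 0.933 and EBP at 0.988. Interferon response genes had -0.24 (percentile 40.7), with IFIT5 at 1.21, IRF1 at 0.848 and UBE2L6 at 0.591, and turned positive (0.06) after quantile normalization. Inflammatory genes had -0.01 (percentile 59.6), with SOD2 at 1.53, TRAF1 at 0.991 and IRF1 at 0.848. Growth factors and their receptors also had -0.01 (percentile 71.9), with BMP2 at 1.56, TGFBR2 at 0.995 and VEGFB at 0.789. Both of these lists had positive medians after division by the median, quantile normalization or loess.

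Over all 5 ratios, 1 of 60 list medians lay outside the central 95%, where 3.0 would by chance. It belonged to the aminoacyl-tRNA synthetase list in the serum to control ratio of polysomes, with a median log2 of -0.55 (percentile 2.2). Its members, which charge tRNAs with amino acids or support that complex, were WARS1 at 0.639, IARS1 at 0.684 and AIMP1 at 0.979.

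Endothelial markers had a median log2 index of -0.17 (percentile 52.8), with all 3 below 1, namely the junctional cadherin CDH5 at 0.965, the transcription factor FLI1 at 0.887 and the protein C receptor PROCR at 0.884. CDH5 intensities were 1.01, 1.13, 0.92 and 1.08 in control monosomes, control polysomes, serum monosomes and serum polysomes, all near the filter median. Of 29 genes fixed for reporting, 5 were named on the array, and the vascular receptor KDR (intensities 0.76 to 0.93) and the transcription factor JUN (0.8 to 1.09) did not pass the filter. Of other cell types, CSF1R was the only leukocyte marker past the filter (index 2.65), CNN1 the only smooth muscle marker (1.22) and LUM the only fibroblast marker (0.68), while 0 platelet or erythroid markers were named on the array.

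The remaining lists had at most 2 genes past the filter. Indices were 0.827 for the ribosomal protein gene RPL31, 2.5 for BTF3 and 1.73 for CCNI among other terminal oligopyrimidine mRNAs, and 0.811 for EIF2B5 and 0.796 for EIF4G1 among initiation factors. CDK6, a kinase of cell cycle entry, had 0.395 and the mitotic kinesin KIF11 had 1.04. The glycolytic genes LDHA and PFKL had 1.08 and 0.745, the chaperones CCT6A and DNAJB1 had 0.833 and 1.13, and the vascular gene ECE1 had 1.28 beside PROCR. Neither of the 2 listed growth mRNAs that depend on the cap-binding initiation factor passed the filter.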

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

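The tests on the translation index in this part were chosen after the index had been seen. For 17 of the 24 genes with the highest or lowest translation index, the polysome to monosome ratio lay above 1 in one condition and below 1 in the other. The difference was not tested, since each ratio rests on 1 filter per fraction. The genes were picked for a large difference between the 2 ratios, whose median log2 values were 0.07 in control and -0.05 in serum. Lying on opposite sides of 1 therefore follows in part from the picking. Because each filter was divided by its own mean, a ratio of 1 does not mean equal amounts in the fractions.

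The ratio was below 1 in control and above 1 in serum for FGF1 (index 13.6), PIGC (8.8), FASTK (8.22), RTN3 (8.11), MTR (4.56), MAP2K4 (3.36) and MBOAT7 (3.19). It was above 1 in control and below 1 in serum for RAB1A (0.0786), MTMR11 (0.101), DR1 (0.186), LDB2 (0.21), SLC35B1 (0.218), JAG1 (0.232), LMO2 (0.235), CCN1 (0.238), ZNF148 (0.247) and CYB561D2 (0.295). The side of 1 depended on the scaling for 3 of the 17, where division by the median moves all ratios by the same factor. The serum ratio of MAP2K4 was 0.995 after loess, that of DR1 was 1.14 after division by the median, and that of JAG1 was 1.07, 1.08 and 1.11 after division by the median, quantile normalization and loess.

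Signal at background on some filters stays open for indices past a limit. Of the 352 elements with signal above 1.5 times the median on all 4 filters, 30 were past one (8.5%, exact 95% interval 5.8 to 11.9), much as the 68 of 759 with such signal on 1 to 3 filters (9.0%, 7.0 to 11.2). Of the 794 with such signal on no filter, 0 were past one. Signal on only 1 to 3 filters means unequal filters, so the grouping itself shapes these shares and they cannot decide. Independent error of single filters would leave a covariance near 0 between the log2 serum to control ratios of the fractions. It was -0.005 (95% bootstrap interval -0.02 to 0.011). A change with serum in a single fraction would leave it near 0 too, so this test cannot tell them apart. Nor can the shuffles, which keep each fraction's ratios (48 high and 50 low calls, against 53.7 and 58.4 on average). The 4 elements past opposite limits in the fractions lie at the upper end of the shuffles (1.1 on average, central 95% 0 to 4). A movement of mRNAs between monosomes and polysomes with serum could not be decided from repeat elements, because 0 of the 12 genes with several elements had an element past a limit. An earlier test by intensity (0 of 635 dim, 19 of 635 middle and 79 of 635 bright elements past a limit) was set aside, because a large value on any filter raises both the mean intensity and the index.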

How the results depend on the processing

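The alternatives with a threshold of 1.5 times the filter median and with the median subtracted were chosen after the results were seen. Counts, SDs, correlations, list medians and single-gene indices were recomputed under the alternatives that apply to them. Limits of 2 and 0.5 were applied to the counts only, and the brightest element of each gene to the list medians only. For the counts, SDs and correlations that answer a comparison, 58 recomputed values differed from the main value by over 1.5 times or lay beyond its bootstrap interval, and 93 did not. Among recomputed medians of single lists, judged by a bootstrap interval over their members, and the indices of single genes, judged by the SD between elements of the same gene, 46 values moved and 278 did not. Many of the 278 could not move. Settings that change only which elements are kept, and the floor, leave the index of each single gene counted here as it was. Division by the median shifts every index by the same amount. The intervals of these small lists are wide, and some list medians changed sign within them, among them that of the proteasome (0.48, but -0.13 without a filter and -0.11 with the floor). That of immediate early genes was -0.35, but 0.15 with signal on all 4 filters, where only CCN1, IER3 and JUNB remained. Except where a setting admits or draws in elements by construction, as said beside it, the cause was not tested. The 24 genes with extreme index kept their direction under quantile normalization, loess, the pseudocount and subtraction, the settings that could change their indices unequally. With the pseudocount 20 of 24 stayed past a limit (not PSIP1, MAP2K4, MBOAT7 and CYB561D2), after quantile normalization 23 of 24 and after loess all 24. The stricter filter left 20 of the 24 with a value and signal on all 4 filters left 6, and lists with fewer than 3 genes had no value there. The labels give no replicate numbers, so no fit with a replicate block was made. Signal over background limits what the filters can show, since most intensities lie near the filter median.

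Counts are given as high and low. With the filter median subtracted, the index had 152 and 282, the control translation state 465 and 124, the serum translation state 362 and 138, the monosome serum to control ratio 118 and 78, and the polysome ratio 119 and 134. These counts cover 1277 elements in place of 1905. With subtraction the SD between elements of the same gene was 1.53 and the correlation of translation states 0.46. With signal on all 4 filters the same counts were 18 and 12, 66 and 18, 53 and 17, 2 and 7, and 7 and 12, with a correlation of 0.68, among 352 elements in place of 1905. With limits of 2 and 0.5, which admit more elements, they were 79 and 103, 241 and 60, 193 and 52, 28 and 47, and 52 and 67. Signal on at least 1 filter, the same 1277 elements as under subtraction, gave an SD of 1.06 between elements of the same gene.

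After loess the control translation state had 58 and 67, the serum translation state 48 and 54, and their correlation was 0.47. After quantile normalization these were 73 and 59, 64 and 58, and 0.47, with 22 high in the monosome ratio and 21 low in the polysome ratio. With the pseudocount, which draws dim ratios toward 1, the index had 31 and 28, the control translation state 71 and 22, the serum translation state 60 high, the monosome ratio 5 and 10, and the polysome ratio 13 low. The SD between elements of the same gene was 0.67 with the floor and 0.72 without a filter. Under each of those settings 1 list lay outside the central 95% for the index, the leukocyte markers (4 genes, median log2 0.48 at percentile 98.5 with the floor, 0.46 without a filter).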

Other observations

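The test of array background in this part was chosen after the result was seen. Beyond the genes named by rule, 6 more with a translation index past a limit were picked out after their values were seen. The actin-binding gene CNN3 had an index of 3.14, and PDK2, which inhibits pyruvate dehydrogenase, had 2.96. USP5, which disassembles ubiquitin chains, had 0.319, the membrane protease gene ADAM15 0.37, the splicing gene SNRPN 0.387 and the zinc finger gene ZNF354A 0.397. PDK2 reached an intensity of 4.27 in serum polysomes against 1.29 or less on the other filters, and USP5 reached 2.93 in control polysomes against 1.22 or less elsewhere.

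For the likeness of the translation states in the 2 conditions no biological explanation was tested. A trend of the ratio with signal level was tested by loess, after which the correlation across elements was 0.47 (0.41 to 0.52), where such a trend as sole source would leave 0.1 or less. Array background that compresses dim ratios alike was tested in 352 elements with signal on all 4 filters, and the correlation there was 0.68 (0.6 to 0.75). A difference in processing of the fractions cannot be told apart from the fractions themselves, because 0 labels give a batch or day and each fraction of each condition is 1 filter.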
